A study of Rattus norvegicus with 14 samples.

How the data were processed

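Expression was measured in 14 pools of whole epididymides of Sprague-Dawley rats, 3 at day 7, 4 at day 18, 4 at day 28 and 3 at day 60, with 1 Affymetrix RatGene 2.0 ST array per pool. The labels say that frozen tissue gave total RNA, which was treated with DNase, amplified and labelled with biotin; how many animals made up a pool is not in the labels. The authors processed the arrays with RMA (background correction, quantile normalization and median polish as in the published method) and name the Transcriptome Analysis Console, per the labels and without versions, and the deposited values are log2 signals. The settings and the annotation version they used are not in the labels. The table holds 36685 transcript clusters with a value in every array, and no 2 arrays are identical. Array medians ran from 5.21 to 5.42. Pools of 1 age correlated with each other at 0.989 to 0.995 across the 18166 genes that were tested (1 cluster per gene), which are not independent replicates.

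Gene symbols came from the annotation given with the array's clusters: 18511 clusters had 1 symbol, 575 had several and 17599 were not listed. Of the clusters with 1 symbol 18394 matched a RefSeq gene through the gene identifier, and no symbol changed. Where a gene had several clusters (291 genes) the cluster with the highest mean over all 14 arrays was used, which gave 18166 genes; no gene was removed for low signal, and clusters with several symbols or none were left out except in an alternative. Control clusters cannot be recognised in the table, so that alternative used all 36685. Signal over background was gauged from 1344 olfactory and vomeronasal receptor genes, which the tissue is not known to express at high levels. Their median was 2.99 and their 95th percentile 4.92, and 13168 of the 16822 other genes lay above that level. No coordinates are given, because no genome build is named for the array.

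One linear model with a mean for each age was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with neither an intensity trend nor robust hyperparameters). The 3 neighbouring-age differences were tested two-sided with limma's moderated test and together with its F test, and p was adjusted by Benjamini-Hochberg over the 18166 genes, with a threshold of 0.05. A difference of 1 on the log2 scale is called 2-fold and one of 3 is called 8-fold; errors of levels are SDs over pools and errors of differences are SEs of the fit. There were 24 gene lists, with 688 of 791 members measured: luminal secretory proteins, beta-defensins, basal cells, clear and narrow cells, ciliated cells, tight junctions, gap junctions, fluid and solute transport, endoplasmic reticulum protein folding, antioxidant enzymes, steroid receptors and enzymes, Wolffian duct and positional transcription factors, imprinted growth genes, Wnt, Notch and BMP signalling, cell cycle, extracellular matrix, smooth muscle, endothelium, macrophages, antigen presentation, T lymphocytes, red blood cells, adipocytes and haploid germ cells. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 24 lists of a comparison; a member counts as risen or fallen by its own adjusted p over all genes, and the count adjusted over the list alone stands beside it. An estimated correlation kept 18 of the 43 calls. The genes Srd5a2, Krt5 and Acta2, members of these lists, had no cluster with a single symbol and were not analysed here.

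The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, for each comparison, the 10 largest rises and the 10 largest falls with an adjusted p under the threshold, a change of at least 2-fold and no overlap between the values of the ages, and the 2 largest called rises and falls of each list; 1 predicted locus among the rises to day 18 was passed over. Values are printed for all of the first kind and for examples of the second, and other list members are named where a list is described. The alternatives were quantile normalization of the table, centring of each array on its median, only genes at or above the median level, an intensity trend with robust hyperparameters, only the pools of the ages compared, the replicate number as a block, array weights, the mean of a gene's clusters, every cluster, a minimum fold of 1.5, an estimated correlation in camera, and leaving out each of the 14 pools in turn. The analysis was tested on simulated data of the same layout with 200 of 18166 genes changed for each comparison and noise drawn separately for each gene. Far more genes were called in the real data, so the shares that follow need not hold there. For day 18 against day 7 it recovered 91% of log2 differences of 1 and 50% of those of 0.5, for day 28 against day 18 it recovered 93% and 60%, and for day 60 against day 28 it recovered 96% and 51%, with 3.42%, 4.38% and 3.29% false genes among those called. Random lists matched on level were drawn 10000 times from 20 bins of mean level, and bootstrap intervals are 95% intervals of 10000 draws. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.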

Results

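The data cover gene expression in the rat epididymis, the duct in which spermatozoa that leave the testis mature and are stored, at 4 postnatal ages. RNA came from pools of whole epididymides of Sprague-Dawley rats, so each value mixes epithelium, stroma, muscle, vessels, immune cells and anything in the lumen. There were 3 pools at day 7, 4 at day 18, 4 at day 28 and 3 at day 60, and each pool was measured on its own RatGene 2.0 ST array. The table holds 1 log2 signal per transcript cluster and array for 36685 clusters, and the array medians lie between 5.21 and 5.42. The number of pools limits the precision, and the spread between pools is the replicate error in every comparison. The 3 comparisons of neighbouring ages ask which genes change at each step of postnatal development, and a joint test asks which change at all.

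The pools of each age lay together and the ages followed each other along the first principal component, which held 62.8% of the variance of the 18166 genes. The day 7 pools had scores of -67.5 to -67.4 on it and the day 60 pools scores of 49.7 to 51.7. Replicate 2 of day 28 stood apart from the other day 28 pools on the third component (6.07% of the variance), with a score of -25.2 against -15.9 to -14.2. On the first component it also lay nearest the day 60 pools, with a score of 29.7 against 24.5 to 26.5.

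**Figure D1:**
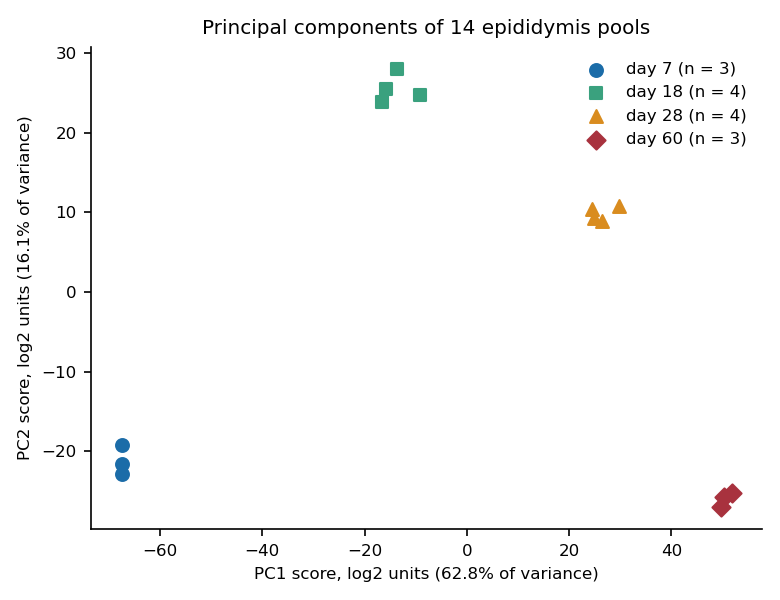
Scores of the 14 pools on the first and second principal components (62.8% and 16.1% of the variance of 18166 genes, log2 units), with 1 point per pool and 1 colour per age. The day 7 pools sit at the left end of the horizontal axis, between -67.5 and -67.4, and the day 60 pools at the right end, between 49.7 and 51.7.

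Between day 7 and day 18 most of the largest rises were in genes of secreted epididymal proteins. Crisp3, which encodes a cysteine-rich secretory protein, went from 3.97 ± 0.12 to 10.79 ± 0.56 (log2 signal, mean ± SD, 3 and 4 pools), a 113-fold rise (adjusted p = 9.92e-12). Its day 7 mean lay under the background level of 4.92. The same holds for the earlier means of Atp6v0d2, Pate5, Defb42 and Smcp, whose fold rises are given further on, so the sizes of these folds are uncertain. Other rises given as log2 differences start under that level too. Examples are Rnase12, Adam7 and Defb44 at day 7, and Defb15 and Defb22 at day 18. Further examples are Cst11, St6galnac1, Odf1 and Tnp1 at day 28. The sizes of these rises are uncertain as well, however small their SE. Serpina16, of the serpin family of protease inhibitors, rose by 6.64 ± 0.20 (log2 difference ± SE), and Rnase12, of the ribonuclease A family, by 5.98 ± 0.17. Lcn5, a lipocalin that binds retinoic acid, rose by 5.41 ± 0.16 and Adam7, of the ADAM family, by 5.26 ± 0.14. Of the luminal secretory proteins 26 of 42 rose and 1 fell (27 and 1 adjusted over the list alone, list adjusted p = 2.32e-16). The member that fell was Mfge8, a milk fat globule protein that cells outside the epithelium also make, which fell by 0.29 ± 0.076. Of the beta-defensins, small antimicrobial peptides, 26 of 36 rose and 0 fell (28 and 0 adjusted over the list alone, list adjusted p = 2e-15). Defb44 rose by 5.65 ± 0.20 and Defb1 by 5.13 ± 0.10. The other genes among the 10 largest rises were Bin2a (5.84), Serpina1fl1 (5.66) and Pate6l (5.60).

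**Figure D2:**
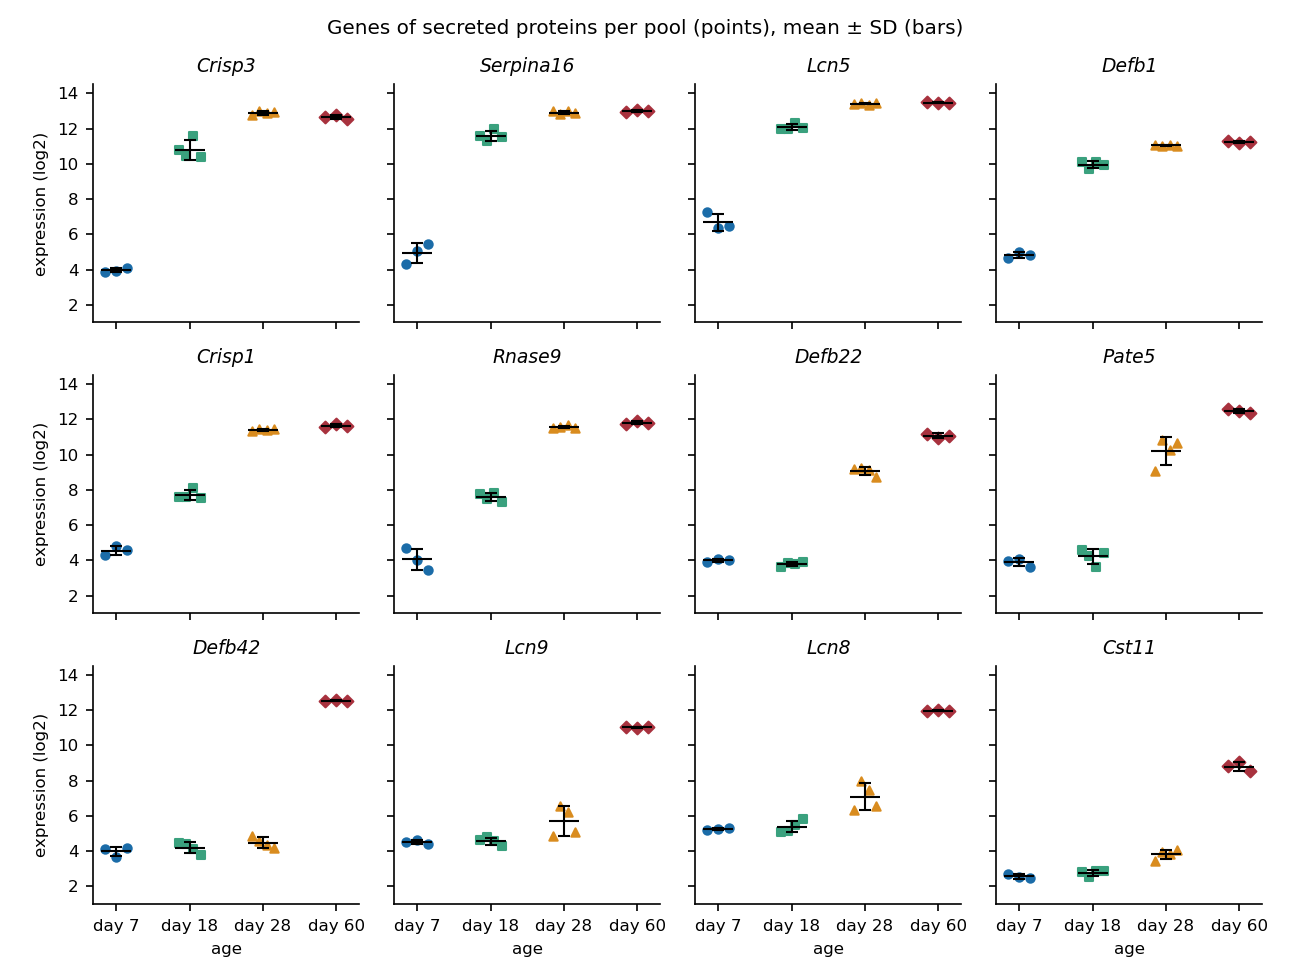
Log2 signal (vertical axes) of 12 genes of secreted proteins in each pool at day 7, 18, 28 and 60 (horizontal axes), with 1 point per pool and bars for the mean ± SD of 3 or 4 pools. Crisp3 and Serpina16 rose by 6.82 and 6.64 between day 7 and day 18, Pate5 and Defb22 by 5.96 and 5.28 between day 18 and day 28, and Defb42 and Lcn9 by 8.05 and 5.33 between day 28 and day 60. Lcn5, Defb1, Crisp1, Rnase9, Lcn8 and Cst11 are drawn in the same way.

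Genes of proton-secreting clear and narrow cells moved up over the same step: 10 of 17 rose and 0 fell (11 and 1 adjusted over the list alone, list adjusted p = 5.28e-09). Atp6v0d2, a subunit of the vacuolar proton pump, rose 21-fold, from 4.14 ± 0.40 to 8.53 ± 0.040 (adjusted p = 1.91e-11), and Hepacam2 rose by 3.62 ± 0.11. Of the fluid and solute transport genes 21 of 39 rose and 4 fell (21 and 4 adjusted over the list alone, list adjusted p = 1.1e-05). The water channel Aqp9, which is also a member of the secretory list, rose by 3.95 ± 0.094 and the anion exchanger Slc26a3 by 2.76 ± 0.087, while Aqp1 fell by 1.18 ± 0.19. Of the genes of protein folding in the endoplasmic reticulum 25 of 47 rose and 5 fell (26 and 5 adjusted over the list alone, list adjusted p = 2.63e-05). Dnajc10 rose by 1.07 ± 0.068, and Creb3l1, a transcription factor of secretory and matrix-forming cells, fell by 1.41 ± 0.098. Of the tight junction genes 14 of 28 rose and 4 fell (14 and 4 adjusted over the list alone, list adjusted p = 0.007, adjusted p = 0.218 with an estimated correlation). Cldn23 and Cldn3 rose by 2.22 ± 0.10 and 1.25 ± 0.082, and Cldn6 and Cldn9 fell by 1.76 ± 0.12 and 1.70 ± 0.14. The gap junction list did not pass its test, and 5 of 17 rose and 1 fell (5 and 2 adjusted over the list alone, list adjusted p = 0.17). The antioxidant enzymes did not pass either, and 14 of 43 rose and 15 fell (14 and 15 adjusted over the list alone, list adjusted p = 0.447). Within them the glutathione transferases Gsta1 and Gsta3 rose by 2.40 ± 0.099 and 2.31 ± 0.098 and Hmox1, haem oxygenase, fell by 1.10 ± 0.17.

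Basal cell genes and genes of steroid receptors and enzymes passed the list test by a small margin. Of the basal cell genes 6 of 16 rose and 2 fell (6 and 2 adjusted over the list alone, list adjusted p = 0.0468, adjusted p = 0.239 with an estimated correlation). Tp63, a transcription factor of basal cells, rose by 2.20 ± 0.10 and Krt14 by 1.98 ± 0.12, while Ngfr and Itgb6, which other cell types also express, fell by 1.45 ± 0.11 and 1.35 ± 0.12. Of the steroid genes 11 of 31 rose and 5 fell (12 and 5 adjusted over the list alone, list adjusted p = 0.0468, adjusted p = 0.253 with an estimated correlation). Fkbp5, a co-chaperone of steroid receptors, rose by 1.34 ± 0.074, and Esr1, an oestrogen receptor, fell by 0.72 ± 0.17. Without 1 pool the basal cell call ended for day 7 replicate 2 (adjusted p = 0.0547), day 7 replicate 3 (0.0745), day 18 replicate 1 (0.0537), day 28 replicate 2 (0.0537), day 60 replicate 1 (0.0509) and day 60 replicate 3 (0.0515). It also ended among genes at or above the median level (adjusted p = 0.123), with array weights (0.0545) and with the pools of the 2 ages alone (0.064). The steroid call ended without day 7 replicate 2 (adjusted p = 0.0677), day 7 replicate 3 (0.0542), day 18 replicate 2 (0.0609), day 28 replicate 2 (0.0514), day 60 replicate 1 (0.0528) and day 60 replicate 3 (0.0515), and with array weights (0.0526) and the pools of the 2 ages alone (0.0715).

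Genes of extracellular matrix, growth and division fell between day 7 and day 18. Of the matrix genes 1 of 39 rose and 36 fell (1 and 36 adjusted over the list alone, list adjusted p = 1.18e-19). Vcan, a large matrix proteoglycan, fell by 2.71 ± 0.17 and Postn, a matrix protein of growing connective tissue, by 1.74 ± 0.092. Of the imprinted growth genes 0 of 17 rose and 15 fell (1 and 15 adjusted over the list alone, list adjusted p = 1.84e-11). Dlk1 fell by 3.04 ± 0.15 and Igf2, a fetal growth factor, fell from 11.20 ± 0.13 to 8.64 ± 0.059, 5.9-fold lower (adjusted p = 9.92e-12). Among the members that fell, Igf2bp1, Igf2bp2 and Hmga2 are fetal growth genes that are not imprinted, and Gnas is a locus of several overlapping transcripts whose cluster (fell by 2.68 ± 0.19) was not traced to one of them. Of the cell cycle genes 0 of 42 rose and 38 fell (0 and 40 adjusted over the list alone, list adjusted p = 1.75e-15, adjusted p = 0.0686 with an estimated correlation). Tpx2, of the mitotic spindle, fell by 1.13 ± 0.13 and Ect2, of cytokinesis, by 1.08 ± 0.096. Of the Wolffian duct and positional transcription factors 5 of 26 rose and 17 fell (5 and 17 adjusted over the list alone, list adjusted p = 0.000188), with Osr1 and Meis1 lower by 4.15-fold and 2.66-fold and Tfcp2l1 higher by 3.07-fold. Of the Wnt, Notch and BMP signalling genes 11 of 56 rose and 27 fell (11 and 28 adjusted over the list alone, list adjusted p = 0.000543, adjusted p = 0.0694 with an estimated correlation). The ligands Wnt9b and Inhba fell by 1.88 ± 0.18 and 1.87 ± 0.13, and Lef1 rose by 1.36 ± 0.13. Of the smooth muscle genes 1 of 17 rose and 11 fell (1 and 12 adjusted over the list alone, list adjusted p = 0.000464, adjusted p = 0.278 with an estimated correlation), among them Myocd, which fell by 1.37 ± 0.14. Of the endothelial genes 1 of 18 rose and 13 fell (1 and 13 adjusted over the list alone, list adjusted p = 2.2e-05, adjusted p = 0.0527 with an estimated correlation), among them Cdh5, which fell by 1.07 ± 0.072.

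The single largest fall was that of Fos, an immediate early transcription factor, from 10.76 ± 0.24 to 6.89 ± 0.14, 14.6-fold lower (adjusted p = 1.05e-10). It was followed by Lgals2 (-3.46), Dcx (-3.29), Zfp575 (-3.11), P4ha3 (-3.10), Bpifc (-3.04), Kcnip4 (-3.04), Dlk1 (-3.04), Smr3a (-2.84) and Cxcl13 (-2.81), each as the log2 difference. Immediate early genes, which respond to handling and stress and were listed only after the values had been seen, moved with the matrix, growth and vessel genes: 4 of 45 rose and 28 fell, adjusted p = 2.04e-07 (adjusted p = 0.161 with an estimated correlation). Genes of mesothelium, the covering of the organ, were listed after the values had been seen as well and moved with the same groups: 2 of 19 rose and 17 fell, adjusted p = 1.6e-08 (adjusted p = 0.0299 with an estimated correlation).

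Genes of antigen presentation and of T lymphocytes rose between day 7 and day 18. Of the first list 20 of 23 rose and 0 fell (20 and 0 adjusted over the list alone, list adjusted p = 7.97e-12). The class II genes RT1-Da and Cd74 rose by 2.35 ± 0.11 and 1.94 ± 0.10. Of the second 19 of 23 rose and 0 fell (19 and 0 adjusted over the list alone, list adjusted p = 2.71e-08). Gzma, a granzyme of cytotoxic lymphocytes, rose by 2.11 ± 0.17 and Cd7 by 2.01 ± 0.13. Macrophage genes as a list did not pass, and 4 of 22 rose and 4 fell (4 and 4 adjusted over the list alone, list adjusted p = 0.561). Ptprc, a marker of all leukocytes, rose by 1.14 ± 0.095, and Cd14 fell by 0.78 ± 0.080. Of the adipocyte genes 13 of 22 rose and 0 fell (13 and 0 adjusted over the list alone, list adjusted p = 0.000361, adjusted p = 0.283 with an estimated correlation). Adipoq, adiponectin, rose by 2.68 ± 0.39 and its SD among the day 18 pools was 0.87, and Thrsp, a regulator of fatty acid synthesis that is not limited to adipocytes, rose by 3.37 ± 0.075. The 3 remaining lists did not pass. For red blood cells 2 of 14 rose and 4 fell (2 and 5 adjusted over the list alone, list adjusted p = 0.32). For ciliated cells 3 of 21 rose and 5 fell (3 and 5 adjusted over the list alone, list adjusted p = 0.544). For haploid germ cells 1 of 32 rose and 1 fell (0 and 0 adjusted over the list alone, list adjusted p = 0.406).

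The test called 3167 genes higher and 3762 lower at day 18 (38.1% of the genes), of which 513 and 557 differed at least 2-fold and 53 and 8 at least 8-fold. With the arrays centred on their medians the counts were 2486 and 3954, so that the share of called genes that were higher went from 45.7% to 38.6%. A gene's SE had a median of 0.111 on the log2 scale. In simulated data of the same layout, with 200 changed genes, the test recovered 91% of log2 differences of 1. Far more genes were called in the real data, so that share need not hold for them. Defensin, serpin, Crisp and Pate genes resemble their paralogs, and signal shared between family members was not separated.

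**Figure D3:**
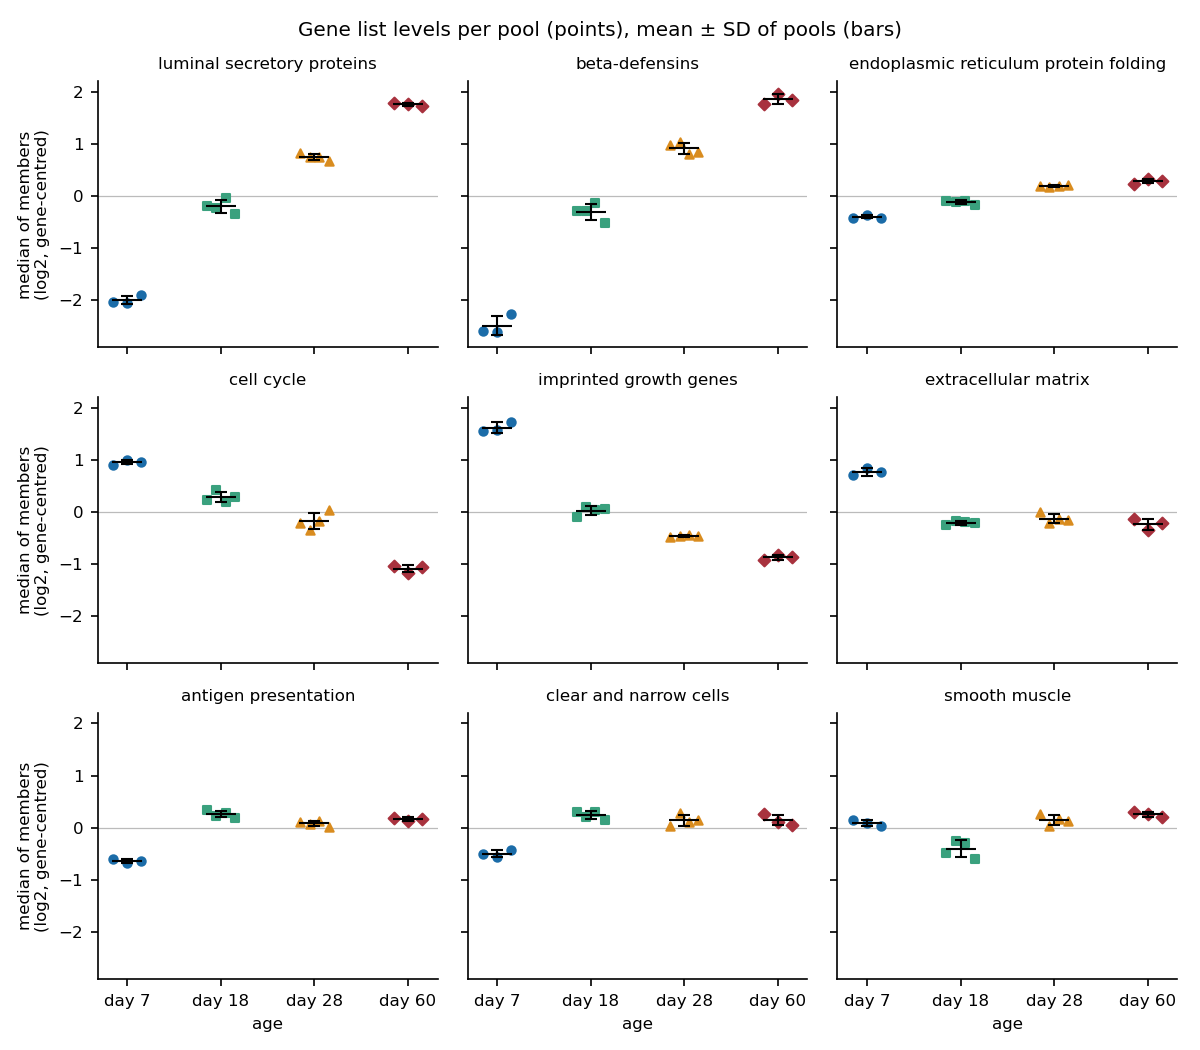
Median of the members of 9 gene lists in each pool (vertical axes, log2 signal after each gene's mean over the 14 pools is taken off) at day 7, 18, 28 and 60 (horizontal axes), with 1 point per pool and bars for the mean ± SD of 3 or 4 pools. The luminal secretory list lies between -2.04 and -1.89 at day 7 and between 1.73 and 1.79 at day 60, and the cell cycle list between 0.908 and 0.995 at day 7 and between -1.17 and -1.04 at day 60.

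Between day 18 and day 28 secretory genes rose again, and the chloride channel gene Gabrp had the largest fall. Pate5, of the prostate and testis expressed family of small secreted proteins, went from 4.23 ± 0.44 to 10.19 ± 0.78 (log2 signal, mean ± SD, 4 pools each), a 62.4-fold rise (adjusted p = 4.03e-09). Defb15 rose by 5.96 ± 0.27, Defb22, a sperm-coating defensin, by 5.28 ± 0.11 and Cstdc2 by 5.47 ± 0.31 (log2 ± SE). The remaining largest rises were Serpina1fl2 (5.18), Ly6g5c (5.13), Defb41 (4.77), Pate2 (4.75), Pate10 (4.45) and Clpsl2 (4.34). Of the luminal secretory proteins 31 of 42 rose and 2 fell (33 and 2 adjusted over the list alone, list adjusted p = 2.53e-19). Spag11a rose by 4.03 ± 0.22, Rnase9 by 3.97 ± 0.19 and Crisp1 by 3.70 ± 0.12, and Wfdc2, a whey acidic protein, fell by 1.79 ± 0.081. Of the beta-defensins 20 of 36 rose and 2 fell (23 and 3 adjusted over the list alone, list adjusted p = 8.76e-17). Of the genes of protein folding in the endoplasmic reticulum 32 of 47 rose and 0 fell (34 and 0 adjusted over the list alone, list adjusted p = 4.56e-16). Agr2, a disulfide isomerase of secretory cells, rose by 2.19 ± 0.18, Derl3 by 1.59 ± 0.18 and the chaperone Hspa5 by 0.47 ± 0.064.

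Gabrp, a subunit of a chloride channel gated by GABA, fell from 9.90 ± 0.14 to 6.59 ± 0.34, 9.95-fold lower (adjusted p = 1.28e-09). Mmp7, a matrix protease, fell by 2.67 ± 0.53, Ass1, of arginine synthesis, by 2.54 ± 0.13, and Wnt9b, a ligand of the Wolffian duct, by 2.49 ± 0.16. The others were Alox15b (-2.25), Sfta2 (-2.17), Cldn6 (-2.03), Kcnj16 (-1.93), Ifgga4l (-1.92) and Alox15 (-1.82). Of the fluid and solute transport genes 15 of 39 rose and 7 fell (15 and 9 adjusted over the list alone, list adjusted p = 0.0246, adjusted p = 0.3 with an estimated correlation). The carnitine transporter Slc22a5 and the sodium-proton exchanger Slc9a2 rose by 1.66 ± 0.084 and 1.21 ± 0.13, and the chloride channel Cftr fell by 1.68 ± 0.11. This call ended among genes at or above the median level (adjusted p = 0.295). Tight junctions did not pass, and 4 of 28 rose and 9 fell (4 and 11 adjusted over the list alone, list adjusted p = 0.194). Within that list Cldn2 rose by 1.97 ± 0.16 while Cldn6 fell. For gap junctions, which did not pass, 1 of 17 rose and 4 fell (1 and 4 adjusted over the list alone, list adjusted p = 0.444). For basal cells, which did not pass, 6 of 16 rose and 3 fell (6 and 5 adjusted over the list alone, list adjusted p = 0.169). For clear and narrow cells 3 of 17 rose and 7 fell (3 and 8 adjusted over the list alone, list adjusted p = 0.118). This last list was called lower among genes at or above the median level (adjusted p = 0.0394). Krt15 rose by 1.39 ± 0.17, the ammonia channel Rhcg by 1.56 ± 0.099, and Foxi1, a transcription factor of proton-secreting cells, fell by 1.29 ± 0.087.

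Cell cycle genes fell again, and the smooth muscle and endothelial lists were called higher. Of the cell cycle genes 0 of 42 rose and 31 fell (0 and 34 adjusted over the list alone, list adjusted p = 3.46e-12, adjusted p = 0.229 with an estimated correlation). Aurkb, a mitotic kinase, fell by 0.80 ± 0.10 and Mcm5, of DNA replication, by 0.77 ± 0.15. Of the imprinted growth genes 0 of 17 rose and 10 fell (0 and 10 adjusted over the list alone, list adjusted p = 5.66e-05). Igf2 fell by 1.06 ± 0.075, and Igf2bp2, which is not imprinted, was 2.83-fold lower. Of the smooth muscle genes 13 of 17 rose and 0 fell (14 and 0 adjusted over the list alone, list adjusted p = 2.82e-09, adjusted p = 0.195 with an estimated correlation). Myh11, smooth muscle myosin, rose by 0.96 ± 0.14 and Pgm5 by 0.93 ± 0.086. Of the matrix genes 6 of 39 rose and 2 fell (6 and 2 adjusted over the list alone, list adjusted p = 0.00722, adjusted p = 0.379 with an estimated correlation), with Col15a1 higher by 0.77. Of the endothelial genes 6 of 18 rose and 0 fell (8 and 0 adjusted over the list alone, list adjusted p = 0.00339, adjusted p = 0.275 with an estimated correlation), with Vwf, von Willebrand factor, higher by 0.87. Of the adipocyte genes 9 of 22 rose and 2 fell (12 and 2 adjusted over the list alone, list adjusted p = 0.000386, adjusted p = 0.377 with an estimated correlation), with Thrsp and Dgat2, of triglyceride synthesis, higher by 1.04 and 0.84. Of the antioxidant enzymes 12 of 43 rose and 5 fell (13 and 6 adjusted over the list alone, list adjusted p = 0.0246, adjusted p = 0.3 with an estimated correlation), with the glutathione transferase Mgst2 higher by 1.14 and Gstm5 2.11-fold lower. The call ended without day 28 replicate 4 (adjusted p = 0.0601). The lists of positional transcription factors, signalling and steroid genes did not pass. For the positional transcription factors 7 of 26 rose and 6 fell (10 and 6 adjusted over the list alone, list adjusted p = 0.14). For steroid receptors and enzymes 9 of 31 rose and 5 fell (10 and 7 adjusted over the list alone, list adjusted p = 0.0997). For the Wnt, Notch and BMP genes 10 of 56 rose and 11 fell (15 and 12 adjusted over the list alone, list adjusted p = 0.883). In the last of these the median log2 difference (0.037) and the test pointed up and the mean (-0.045) down.

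The macrophage and antigen presentation lists were called lower between day 18 and day 28. Of the macrophage genes 2 of 22 rose and 9 fell (2 and 13 adjusted over the list alone, list adjusted p = 0.00641, adjusted p = 0.377 with an estimated correlation). Lyz2, lysozyme, fell by 0.61 ± 0.094, and Siglec1, of resident macrophages, rose by 1.57 ± 0.10. Of the antigen presentation genes 0 of 23 rose and 7 fell (0 and 7 adjusted over the list alone, list adjusted p = 0.0122, adjusted p = 0.3 with an estimated correlation). Psmb10, of the immunoproteasome, fell by 0.76 ± 0.081. The T lymphocyte list did not pass, and 0 of 23 rose and 2 fell (0 and 0 adjusted over the list alone, list adjusted p = 0.235). It was called lower without day 18 replicate 4 (adjusted p = 0.0476). Red blood cells did not pass, and 0 of 14 rose and 1 fell (0 and 1 adjusted over the list alone, list adjusted p = 0.883). Ciliated cells did not pass, and 1 of 21 rose and 5 fell (2 and 5 adjusted over the list alone, list adjusted p = 0.726). Of the haploid germ cell genes 6 of 32 rose and 0 fell (5 and 0 adjusted over the list alone, list adjusted p = 0.017, adjusted p = 0.282 with an estimated correlation). The 3 that rose most, Ddx4 (1.27 ± 0.15), Ldhc (0.99 ± 0.26) and Pgk2 (0.85 ± 0.22), are germ cell genes that are already active before the haploid stage. Their mean signals at day 18 (3.81, 3.86 and 4.22), and that of Ldhc at day 28 (4.85), lay under the background level of 4.92, so the sizes of these rises are uncertain. That call ended with quantile normalization (adjusted p = 0.103) and without day 28 replicate 2 (adjusted p = 0.0674), the pool that stood apart from the other day 28 pools.

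At day 28 the test called 1899 genes higher and 2592 lower than at day 18 (24.7% of the genes), with 283 and 110 of them at least 2-fold and 33 and 1 at least 8-fold. With the arrays centred on their medians the counts were 1339 and 2890, so that the share of called genes that were higher went from 42.3% to 31.7%; without day 28 replicate 2 they were 1938 and 2047.

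Between day 28 and day 60 most of the largest rises were in secretory genes and in genes of haploid germ cells. St6galnac1 and Bpi, also among the largest, are in none of those fixed lists. Defb42, a beta-defensin, went from 4.49 ± 0.29 to 12.55 ± 0.0069 (log2 signal, mean ± SD, 4 and 3 pools), a 266-fold rise (adjusted p = 5.07e-13). Smcp, which encodes a protein of the sperm mitochondrial capsule, rose 70.8-fold from 3.86 ± 0.29, a log2 difference of 6.15 ± 0.16 (adjusted p = 3.92e-12). The lipocalins Lcn9 and Lcn8 rose by 5.33 ± 0.31 and 4.86 ± 0.30 (log2 ± SE), the cystatins Cst11, Cst12 and Cst8 by 4.98 ± 0.15, 4.29 ± 0.26 and 4.26 ± 0.39, St6galnac1, a sialyltransferase, by 5.95 ± 0.12 and Bpi by 4.42 ± 0.15. Of the luminal secretory proteins 17 of 42 rose and 2 fell (20 and 2 adjusted over the list alone, list adjusted p = 8.67e-07, adjusted p = 0.0898 with an estimated correlation). Of the beta-defensins 17 of 36 rose and 4 fell (19 and 4 adjusted over the list alone, list adjusted p = 2.58e-07). Defb20 rose by 3.72 ± 0.29 and Defb11 fell by 0.91 ± 0.13.

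Of the haploid germ cell genes 14 of 32 rose and 1 fell (15 and 1 adjusted over the list alone, list adjusted p = 1.04e-06). Besides Smcp, Odf1, of the sperm tail, rose by 4.41 ± 0.14, Oaz3, a testis antizyme, by 4.15 ± 0.19, and Tnp1 and Prm1, which pack sperm chromatin, by 2.66 ± 0.15 and 2.47 ± 0.17. Ddx4, whose transcript is found before the haploid stage, was at 5.09 ± 0.21 and 4.73 ± 0.13 at the last ages, a difference that did not pass (adjusted p = 0.13).

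**Figure D4:**
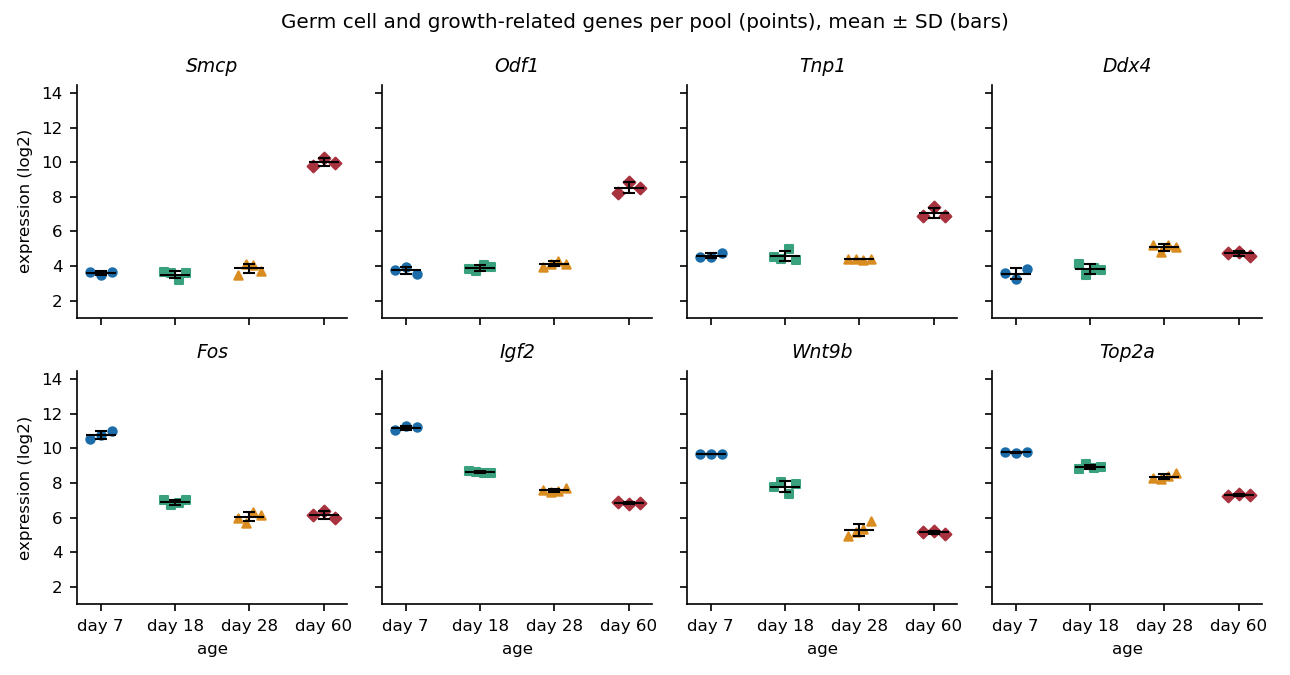
Log2 signal (vertical axes) of 8 genes outside the secretory lists in each pool at day 7, 18, 28 and 60 (horizontal axes), with 1 point per pool and bars for the mean ± SD of 3 or 4 pools. Smcp, Odf1 and Tnp1 rose by 6.15, 4.41 and 2.66 at day 60, Ddx4 rose by 1.27 at day 28, Fos and Igf2 fell by 3.87 and 2.56 at day 18, Wnt9b fell by 2.49 at day 28 and Top2a fell by 1.08 at day 60.

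At this step too the cell cycle genes moved down: 0 of 42 rose and 41 fell (0 and 41 adjusted over the list alone, list adjusted p = 2.15e-30). Ect2 and Cdc20, of mitosis, fell by 1.35 ± 0.096 and 1.30 ± 0.098, and Top2a, the topoisomerase of dividing cells, fell from 8.37 ± 0.15 to 7.29 ± 0.054. Depdc1 and Stmn1 were among the largest falls as well (-1.37 and -1.34), with Pate14 (-1.87), Spink1l (-1.76), Gstm6l (-1.68), Ret (-1.51), H1f5 (-1.39) and Il1rn (-1.37). Fam111a had the largest fall, -2.10, with an SD of 1.79 among the day 60 pools; without day 60 replicate 3 the difference was -1.08 (adjusted p = 0.0143). Of the imprinted growth genes 1 of 17 rose and 10 fell (1 and 10 adjusted over the list alone, list adjusted p = 0.000128). Zim1 fell by 0.93 ± 0.13, and Dlk1 rose by 0.86 ± 0.15. Of the matrix genes 7 of 39 rose and 12 fell (7 and 14 adjusted over the list alone, list adjusted p = 0.0319, adjusted p = 0.528 with an estimated correlation). Postn fell by 0.82 ± 0.092 and Col12a1 rose by 1.12 ± 0.12. The matrix call ended without day 28 replicate 1 (adjusted p = 0.137), without day 60 replicate 2 (0.115) and with the pools of the 2 ages alone (0.0555).

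The macrophage genes moved up: 13 of 22 rose and 0 fell (14 and 0 adjusted over the list alone, list adjusted p = 1.5e-07, adjusted p = 0.0994 with an estimated correlation). Siglec1 rose by 1.30 ± 0.11, the haemoglobin scavenger receptor Cd163 by 1.25 ± 0.094 and Cd14 by 0.95 ± 0.080. Of the T lymphocyte genes 8 of 23 rose and 1 fell (8 and 1 adjusted over the list alone, list adjusted p = 0.0196, adjusted p = 0.482 with an estimated correlation), with Prf1, perforin, higher by 1.09. Of the adipocyte genes 6 of 22 rose and 1 fell (7 and 1 adjusted over the list alone, list adjusted p = 0.0154, adjusted p = 0.528 with an estimated correlation), with Lep, leptin, higher by 1.66. The T lymphocyte call ended among genes at or above the median level (adjusted p = 0.154), as did the adipocyte call (0.219), which also ended without day 28 replicate 3 (0.0871) and without day 60 replicate 1 (0.0605). Of the fluid and solute transport genes 19 of 39 rose and 3 fell (20 and 4 adjusted over the list alone, list adjusted p = 1.92e-05, adjusted p = 0.0657 with an estimated correlation). The sodium-proton exchanger Slc9a3 rose by 1.86 ± 0.20 and the water channel Aqp7 by 1.27 ± 0.15, and Aqp2 fell by 1.21 ± 0.20. Of the antioxidant enzymes 17 of 43 rose and 4 fell (20 and 6 adjusted over the list alone, list adjusted p = 0.00628, adjusted p = 0.162 with an estimated correlation), with Mgst2 higher by 1.85. The call ended among genes at or above the median level (adjusted p = 0.0554).

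The remaining lists did not pass at this step. Of the basal cell genes 1 of 16 rose and 4 fell (1 and 4 adjusted over the list alone, list adjusted p = 0.228). Of the clear and narrow cell genes 1 of 17 rose and 4 fell (2 and 4 adjusted over the list alone, list adjusted p = 0.685). Of the ciliated cell genes 3 of 21 rose and 1 fell (0 and 0 adjusted over the list alone, list adjusted p = 0.907). Of the protein folding genes 12 of 47 rose and 3 fell (14 and 5 adjusted over the list alone, list adjusted p = 0.223). Of the tight junction genes 6 of 28 rose and 4 fell (6 and 4 adjusted over the list alone, list adjusted p = 0.558), and Cldn10 rose by 1.70 ± 0.11. Of the gap junction genes 1 of 17 rose and 3 fell (1 and 3 adjusted over the list alone, list adjusted p = 0.957). Their median (0.055) and mean (0.0003) log2 differences were positive and the test pointed down. Of the smooth muscle genes 1 of 17 rose and 1 fell (1 and 1 adjusted over the list alone, list adjusted p = 0.558). Of the endothelial genes 4 of 18 rose and 0 fell (4 and 0 adjusted over the list alone, list adjusted p = 0.198). Of the antigen presentation genes 5 of 23 rose and 3 fell (5 and 3 adjusted over the list alone, list adjusted p = 0.228). Of the red blood cell genes 2 of 14 rose and 0 fell (2 and 0 adjusted over the list alone, list adjusted p = 0.282). Of the positional transcription factors 2 of 26 rose and 7 fell (2 and 7 adjusted over the list alone, list adjusted p = 0.155). Of the Wnt, Notch and BMP signalling genes 8 of 56 rose and 7 fell (8 and 8 adjusted over the list alone, list adjusted p = 0.255). Of the steroid receptors and enzymes 8 of 31 rose and 2 fell (11 and 3 adjusted over the list alone, list adjusted p = 0.113). They were called higher without day 60 replicate 2 (adjusted p = 0.0464). Sult2b1, a sulfotransferase of sterols, rose by 1.18 ± 0.090.

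At day 60 the test called 2511 genes higher and 2039 lower than at day 28 (25.1% of the genes), with 287 and 68 of them at least 2-fold and 20 and 0 at least 8-fold. With the arrays centred on their medians the counts were 2793 and 1104, so that the share of called genes that were higher went from 55.2% to 71.7%; without day 28 replicate 2 they were 2204 and 2255.

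Over the 4 ages together 10974 of the 18166 genes (60.4%) differed between ages by the joint test. The step with the largest change was from day 7 to day 18 for 5453 of them, from day 18 to day 28 for 2574 and from day 28 to day 60 for 2947. Of the 78 measured secretory and beta-defensin genes 34 had their largest rise, called and at least 2-fold, between day 7 and day 18, 17 between day 18 and day 28 and 11 between day 28 and day 60, and 16 had no such rise. Serpina16 and Lcn5 belong to the first set, Rnase9 and Defb22 to the next and Defb42 and Lcn8 to the last.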

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

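The tests on immediate early genes, on the day 28 pools and on germ cell genes that rose at least 2-fold were chosen after their results had been seen; the other tests on germ cell genes were written before their lists were looked at. In 16 of 356 groups of 4 pools (154 named genes and the 24 list medians, at day 18 and day 28) 1 pool lay far from the others, with a gap to its nearest neighbour, as a share of the group's range, above Dixon's 95% critical value, which chance gives in about 1 of 20 groups. At day 18 replicate 3 was that pool in 7 of 11 cases. It was the high one for Crisp1 (share of the range 0.953), Mfge8 (0.987), Pate10 (0.951, 7.92 against at most 6.45 in the others on the log2 scale), Pate6l (0.894) and Slc22a5 (0.911) and the low one for Kcnip4 (0.874) and Smcp (0.861). The other pools at day 18 were replicate 1 for Cd74 (high, 0.83) and Spag11a (low, 0.882), replicate 2 for Cst11 (low, 0.917) and replicate 4 for Msln (low, 0.854). At day 28 they were replicate 1 for Cstdc2 (low, 0.881), Defb15 (low, 0.839) and Myocd (high, 0.856) and replicate 2 for Cldn23 (low, 0.852) and Spink1l (low, 0.866).

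Haploid germ cell genes were higher at day 60 than at day 28 (14 of 32 rose), Smcp by 6.15 and Odf1 by 4.41 on the log2 scale. For the genes of these lists, the tables argue against testis tissue that raises spermatocyte genes as much as haploid genes. At least 2-fold rises were seen in 2 of 46 spermatocyte genes and 10 of 32 haploid genes (two-sided Fisher's exact test over genes, which are not independent replicates, p = 0.00258). Among the members under background at day 28, 0 of 33 and 9 of 21 rose that far (same exact test, p = 5.53e-05). That comparison was chosen after the haploid rise had been seen. Late spermatid genes fell short of the haploid list too (2 of 35), so the contrast is not particular to spermatocyte genes. Testis tissue carried over in dissection in which spermatocyte RNA is scarcer stays open, since the median log2 difference of the 46 spermatocyte genes, -0.0068 with an upper end of the 95% bootstrap interval of 0.0669, lay under the bound of 0.5 set beforehand, but so did that of the haploid list itself, 0.22, and by limma 3 spermatocyte genes rose and 2 fell (camera adjusted p = 0.979) and of Sertoli and Leydig cell genes 2 of 20 rose and 3 fell. RNA of late spermatids or spermatozoa stays open as well: a list of 35 late spermatid genes, none in the haploid list, had a median of 0.077, at percentile 99.8 of random lists of matched level (median -0.068), though 2 of its genes rose at least 2-fold, fewer than in the haploid list by the same exact test (p = 0.00956), 7 rose and 0 fell in all, and its limma camera test did not pass (adjusted p = 0.16). The late spermatid list had 9 of its 35 genes above the background level at day 28 and 9 at day 60. The haploid list had 11 and 20 of its 32 genes above it. Most late spermatid genes thus lay at background, which limits what that list's median can show. A change with age in the epididymis itself was not tested against these explanations.

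Immediate early genes were lower at day 18 than at day 7 (28 of 45 fell, 4 rose), Fos by -3.87. A handling response stays open, and the test on it cannot decide. The genes' SD among the 3 day 7 pools had a median of 0.151 against 0.0825 for random lists of matched level, at percentile 100. The SD was not compared at the other ages, so the excess is not shown to be particular to day 7. A response shared by all day 7 pools would not show in that SD. A spread between those pools does not by itself give a fall from all of them. With each gene's mean over all pools taken off, the list's median was 0.4495 to 0.6762 in the day 7 pools. In the day 18 pools it was -0.0794 to 0.0093. A larger share of stroma at day 7 stays open too: the list's median log2 difference, -0.53, lay above that of the matrix genes, -1.03, by 0.49 with a 95% interval of 0.149 to 0.822, but its members went both ways, so the median does not decide, and Fos fell further than each of the 39 matrix genes (Vcan, the furthest, by -2.71). Age, as the labels give it, was not tested apart from these.

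Replicate 2 of day 28 stood apart from the other day 28 pools, with its dimmest genes higher than their mean (median log2 deviation 0.112) and its brighter genes lower (-0.145). A first form of the test, which chose genes by day 60 against the other day 28 pools, separates nothing, since the rising genes lay at percentile 100 in replicates 2, 3 and 4 and 3.21 in replicate 1, and the falling genes at percentile 0 in replicates 1 and 2, 3.22 in replicate 3 and 100 in replicate 4. A second form, chosen after that, took genes by day 60 against day 18: in replicate 2 the 763 rising genes deviated by -0.040 against -0.097 for lists of matched level (percentile 100) and the 410 falling genes by -0.170 against -0.113 (percentile 0). This form separates nothing either, since the rising genes lay at percentile 0 in replicate 1, 99.98 in replicate 3 and 0.17 in replicate 4, and the falling genes at percentile 100 in replicate 4. Compressed array signal and a pool further along in development, for which the lower percentile of both lists, the second from the top, was 100, both stay open.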

How the results depend on the processing

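All alternatives were planned, and the tests of calls are those of limma. Leaving out each of the 14 pools in turn kept 182 of 182 gene counts within 1.5 times: day 18 against day 7 had 2595 to 3386 genes higher and 3255 to 3981 lower, day 28 against day 18 had 1617 to 1938 and 2022 to 2587, and day 60 against day 28 had 1943 to 2466 and 1488 to 2255. Counts that moved by more are these. Centring on medians gave 1104 lower genes for day 60 against day 28; the cause was not tested. Genes at or above the median level, which are fewer, gave 365 2-fold lower genes for day 18 against day 7 and 134 2-fold higher for day 60 against day 28. Every cluster, which are more, gave 920 and 324 2-fold lower for the first steps, and 447 2-fold higher and 196 lower for the last. The minimum fold of 1.5, a stricter test by construction, gave 579 higher and 639 lower, 290 and 112, and 255 and 50, with 44 at least 2-fold lower in the last. Replicate numbers did not pair pools (correlations of residuals of -0.143 to 0.025, and in 1 of 10 pairs of pools with the same number at neighbouring ages the match was the best one); as a block they gave 2969 higher and 3523 lower, 1803 and 2398, and 2258 and 1670. The lowest array weight was that of day 28 replicate 2, 0.346. Lists were not tested with every cluster or with the minimum fold of 1.5. Of 43 list calls 34 held in each of the other alternatives apart from the estimated correlation, and 9 ended in at least 1. Among genes at or above the median level 3 lists had too few genes and were not tested. Lists whose test turned direction were uncalled, and the cause was not tested; their mean log2 differences, which need not turn with the test, were these. For day 60 against day 28 gap junctions had 0.0003, and 0.0337 (quantile normalization), 0.0003 (only the pools of the 2 ages) and -0.0358 to 0.029 (leaving out a pool). Ciliated cells had -0.020, and 0.0415 (quantile normalization), -0.0048 (replicate block), -0.0148 (array weights) and -0.0398 to 0.0028 (leaving out a pool). Smooth muscle had 0.0725, and -0.0036 among genes at or above the median level. For day 28 against day 18 leaving out a pool of any age gave -0.0426 to 0.0089 for red blood cells, -0.1232 to -0.0467 for ciliated cells and -0.0535 to -0.0221 for the Wnt, Notch and BMP genes, and the last 2 kept the sign of the mean. Of 328 results of named genes 0 turned direction; 187 kept their call in each alternative that gave them a value (70 of the 328 had none among genes at or above the median level) and 141 lost it under the minimum fold of 1.5, some of them elsewhere too. Of the 16822 genes other than the 1344 receptor genes that set it, 13168 lay above the background level of 4.92, and fold changes against ages below it are limited by background.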

Other observations

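The gene lists of this part were chosen after the data had been seen, except that the spermatocyte and late spermatid lists and their tests were written before any of their genes was looked at. Genes of cholesterol synthesis rose over the first steps: by day 18 13 of 20 rose and 2 fell, adjusted p = 3.94e-05 (adjusted p = 0.177 with an estimated correlation), and by day 28 14 of 20 rose and 0 fell, adjusted p = 2.46e-09 (adjusted p = 0.0565 with an estimated correlation). Idi1, of isoprenoid synthesis, went from 7.77 ± 0.14 at day 7 to 9.23 ± 0.047 at day 18 and 9.90 ± 0.078 at day 28 (log2 signal, mean ± SD, 3, 4 and 4 pools), and Tm7sf2, a sterol reductase, rose by 1.24 ± 0.10 and 1.32 ± 0.095 (log2 ± SE). From day 28 to day 60 the list did not pass (3 of 20 rose and 4 fell, adjusted p = 0.407 (adjusted p = 0.714 with an estimated correlation)). Ribosomal protein genes fell after day 18: by day 28 0 of 45 rose and 32 fell, adjusted p = 5.93e-13 (adjusted p = 0.0542 with an estimated correlation), and by day 60 0 of 45 rose and 22 fell, adjusted p = 1.07e-09 (adjusted p = 0.124 with an estimated correlation). Rps19 went from 10.90 ± 0.052 at day 18 to 10.40 ± 0.10 at day 28 and 9.57 ± 0.089 at day 60, and from day 7 to day 18 the list did not pass (2 of 45 rose and 13 fell, adjusted p = 0.216 (adjusted p = 0.699 with an estimated correlation)). Of the protein glycosylation genes 16 of 53 rose and 5 fell, adjusted p = 0.00418 (adjusted p = 0.36 with an estimated correlation) from day 28 to day 60, most of all St6galnac1 (5.95 ± 0.12); the earlier steps did not pass (21 of 53 rose and 10 fell, adjusted p = 0.099 (adjusted p = 0.699 with an estimated correlation) for the first, and 15 of 53 rose and 6 fell, adjusted p = 0.0546 (adjusted p = 0.396 with an estimated correlation) for the second).

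Mesothelial genes fell from day 7 to day 28 and rose in part at day 60. At the first step 2 of 19 rose and 17 fell, adjusted p = 1.6e-08 (adjusted p = 0.0299 with an estimated correlation), at the second 2 of 19 rose and 13 fell, adjusted p = 0.000501 (adjusted p = 0.122 with an estimated correlation), and at the last 6 of 19 rose and 1 fell, adjusted p = 0.00968 (adjusted p = 0.36 with an estimated correlation). Msln, mesothelin, had 8.64 ± 0.29 at day 7, 6.68 ± 0.12 at day 18, 5.68 ± 0.22 at day 28 and 6.21 ± 0.075 at day 60, and Upk3b fell by 2.46 ± 0.18 at the first step; Lgals2 is a member too and its fall had been seen before the list was written. Oxidative phosphorylation genes passed at none of the steps by limma's camera (15 of 54 rose and 10 fell, adjusted p = 0.467 (adjusted p = 0.699 with an estimated correlation); 5 of 54 rose and 3 fell, adjusted p = 0.202 (adjusted p = 0.61 with an estimated correlation); 5 of 54 rose and 12 fell, adjusted p = 0.118 (adjusted p = 0.643 with an estimated correlation)). Immediate early genes moved at the later steps as follows: by day 28 3 of 45 rose and 18 fell, adjusted p = 0.000501 (adjusted p = 0.192 with an estimated correlation), and by day 60 11 of 45 rose and 5 fell, adjusted p = 0.172 (adjusted p = 0.643 with an estimated correlation). Genes of Sertoli and Leydig cells, which belong to the testis, did not pass (3 of 20 rose and 2 fell, adjusted p = 0.522 (adjusted p = 0.699 with an estimated correlation); 3 of 20 rose and 2 fell, adjusted p = 0.066 (adjusted p = 0.169 with an estimated correlation); 2 of 20 rose and 3 fell, adjusted p = 0.435 (adjusted p = 0.643 with an estimated correlation)).

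Ddx4, Ldhc and Pgk2 rose at day 28, from mean signals under the background level of 4.92, which Ldhc did not pass at day 28 either, and 1 hypothesis was that immature germ cells were present at that age. A list of 46 spermatocyte genes, none of them among the haploid germ cell genes, had a median log2 difference of 0.051 from day 18 to day 28, at percentile 64.6 of random lists of matched level, which leaves the hypothesis undecided; by their own test 10 of 46 rose and 1 fell, adjusted p = 0.011 (adjusted p = 0.175 with an estimated correlation). From day 7 to day 18 the same list gave 4 of 46 rose and 5 fell, adjusted p = 0.522 (adjusted p = 0.699 with an estimated correlation), and the late spermatid list gave 2 of 35 rose and 3 fell, adjusted p = 0.522 (adjusted p = 0.699 with an estimated correlation) and, from day 18 to day 28, 4 of 35 rose and 0 fell, adjusted p = 0.25 (adjusted p = 0.515 with an estimated correlation).

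The splits of the pools argue against chance alone as the source of the counts of called genes, since the real split gave the most each time. Each comparison of neighbouring ages has 35 splits, so the real one can at best be 1 of 35, and chance is not excluded. The splits also cannot separate age from anything else that differed between the ages. For day 18 against day 7 only the real one, 1 of the 35 splits of the 7 pools, gave as many as 6929 genes, and the highest other gave 3489. At an unadjusted p under the threshold the real split gave 8261 genes and the highest other 6237. For day 28 against day 18 the real one alone, 1 of 35, gave as many as 4491, and the highest other gave 0 by limma at the adjusted threshold and 2671 at an unadjusted p under it, against 6484. For day 60 against day 28 the real one alone, 1 of 35, gave as many as 4550, and the highest other gave 1447. The unadjusted counts there were 6574 for the real split and 4649 for the highest other. Over the 4 ages 1 of 100 drawn splits, the real one, gave as many as 10974, and the highest other gave 2056.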
